A study of Mus musculus with 2 samples.

How the data were processed

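H3K9me3, a histone mark of heterochromatin, was measured by ChIP-seq in stomach from newborn mice (postnatal day 0). Per the labels, 1 group of 2 biological replicates was made from tissue pooled over both sexes: replicate 1 came from 15 mice with 2 technical replicates, and replicate 2 from pooled mice whose number the labels do not state, with 1 technical replicate. The labels give a fragment size range of 300 to 500 bases. No untreated, mutant or other tissue group was included, so the comparisons were between replicates, between peak lists, and between peaks and the genome. Control libraries, alignments and signal tracks were not used here.

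The authors deposited 4 peak lists in narrowPeak format on the mm10 build, per the file headers: 1 for each replicate, 1 for both replicates together without a sample of its own (the pooled list), and 1 called replicated. The aligner, the peak caller, their versions, the filters and the rule that made a peak replicated were not given in the sources used here. The replicate 1 list was derived from its alignments and 2 further input files, and the replicate 2 list from its alignments and 1 further input file, per the file headers, which do not say what kind those inputs were. Each deposited peak carries a fold enrichment, which is a linear ratio over background. The authors also gave each peak a −log10 p-value and a −log10 q-value. The deposited score is a whole number made for display and was not used. Each line also holds the authors' offset of the peak summit, which was not used. Folds and p-values of single peaks are the authors' own. They were used to describe, rank or filter peaks within a list, to describe shared peaks across the replicate lists by correlation, to compare replicated with other peaks of the pooled list, and to estimate background and read weight. The files give no read counts per library, so sequencing depth is unknown and precision rests on the number of peaks in each list.

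Coordinates are those of mm10, and the reference genome was GRCm38.p6 with the GENCODE M21 annotation, whose chromosome lengths were checked against the peaks. The main tests used the peaks on 21 chromosomes, and peaks on other sequence were described separately. A peak was shared when it overlapped a peak of the other list by at least 50% of either. Enrichment was tested by rotating all peaks along each chromosome over bases that are not N, 10000 times with random seed 7, which keeps the number, width and clustering of the peaks. Rotations could also place peaks where reads could not be placed. Ratios to rotation may therefore mix the place of the mark with that of placed reads. The two-sided rotation p cannot go below 0.0002, and p-values were adjusted by Benjamini-Hochberg over 4 gene features or 12 gene lists. Replicated and other pooled peaks were compared by permutation tests with 100000 resamples, two-sided, for which the smallest p is 1e-05. These p-values and the binomial, Poisson and correlation intervals (95%) describe peaks in these libraries and counting error only: peaks are not biological replicates, and with 2 samples no test between animals was possible. A promoter was 1 kb on either side of a transcription start site, and a gene had a peak when its body overlapped 1 by at least 1 base. Gene features were those of protein-coding genes only. Each peak midpoint was counted once, as promoter first, then exon, intron and intergenic. Exon thus means exon outside promoters, and intergenic includes non-coding genes and pseudogenes outside protein-coding genes. Dense regions were the 10 non-overlapping windows of 1 Mb, in steps of 0.5 Mb, with most peak bases.

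The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule named the 20 genes under the replicated peaks of highest fold (1 gene per peak, that of largest overlap), up to 6 members of each list by fold, and up to 4 genes in each of the 3 densest windows. Genes, peaks and regions named outside it were chosen after their values were seen. Of the listed symbols, Phf17, Cblif, Bapx1 and Atp5f1b were absent from the annotation and were left out. The share of repeat-masked sequence, a scan of 671 gene families and of gene biotypes, peaks near chromosome starts, and every use of local background or sequence copies were added after the data had been seen.

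Near-identical copies of peaks in the genome were searched with BLAST+ 2.17.0 (megablast). A copy needed 95% identity over 80% of the peak, and a separate search looked for 50 identical bases elsewhere. The local background of each peak was estimated from the deposited fold and −log10 p with a Poisson model that has a genome background, a weight per read and a pseudocount of 1. The model fitted 100% of the peaks of the replicate 1, replicate 2 and pooled lists within 0.005 of their −log10 p, yet it is an inference from the values and not a stated method of the authors. To gauge how far a choice of peaks by p favours high background, backgrounds were shuffled over the replicated peaks 1000 times. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

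The scripts were tested on simulated data. With no enrichment, made by rotating the real peaks, 1.67% of 240 gene list tests gave p under 0.05. This checks the list test under its own random placement only. The rate is an average over lists, many of which expect few genes, which can lower it. In 5 of 5 simulations with peaks placed in 60 zinc finger genes, at least 60 genes of that list had a peak, with p under 0.05. All 300 seeded shared peaks were found, and the background was recovered within 5% for 100% of 300 simulated peaks. Seeded peaks lay inside those genes or were exact copies, and the backgrounds were simulated from the same Poisson model. These checks therefore test the code and not whether the model holds for the authors' values. Alternatives were the overlap rule, stricter thresholds, lists of equal length, independent placement of peaks, other definitions of a gene with a peak, the pooled list, and each replicate's own list. Restriction to peaks of q of 0.05 or less, to peaks found in both replicates, to peaks without copies or with low background, and to zinc finger genes outside clusters was chosen after seeing the data.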

Results

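H3K9me3 peaks were listed for stomach of newborn mice, in 1 group of 2 biological replicates. Replicate 1 had 19469 peaks with a median width of 230 bases and a median fold enrichment of 2.87. Replicate 2 had 714 peaks, with a median width of 292.5 bases and a median fold of 3.26, so the lists differed 27.3-fold in length. The pooled list held 4669 peaks, and 2324 of these formed the replicated list, of which 2210 lay on chromosomes. Replicated peaks covered 965 kb, and 538 of them (23.1%) had a q-value of 0.05 or less. Such peaks were 10.4% of the replicate 1 list and 10.6% of the replicate 2 list. Of the replicated peaks, 449 (19.3%) overlapped peaks in the lists of both replicates, 1399 only in replicate 1, 107 only in replicate 2 and 369 (15.9%) in neither, so the name of the list does not mean that a peak was called in each replicate.

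The first comparison asked whether the mark was found at the same places in both replicates. Shared places included Klf14, which encodes a Krüppel-like transcription factor, with a peak of fold 5.47 in replicate 1 and 5.08 in replicate 2. The last exon of the zinc finger gene Zfp90 carried a fold of 4.43 in replicate 1 and 4.76 in replicate 2. In Plec, which encodes the cytoskeletal linker plectin, the folds were 4.95 and 4.76. On chromosomes, 356 of 641 replicate 2 peaks (55.5%) overlapped a replicate 1 peak, against a mean of 0.309% over rotations. From the other side, 353 of 19270 replicate 1 peaks (1.83%) overlapped a replicate 2 peak, against 0.0103%. Both rotation p-values were 0.0002, the smallest they can give. By the estimated local background, 12.3% of all replicate 2 peaks and 1.12% of all replicate 1 peaks lay over 3 times the genome background. Sharing was not tested without such peaks, so part of it may come from regions of high background. Across the 356 shared peaks, which are not independent replicates, the log2 folds had a Pearson r of 0.42 (0.334 to 0.505) and a Spearman rho of 0.36. The SD of the log2 difference between replicates was 0.38. With lists of equal length, the share was 23.4% for replicate 2 peaks and 21.8% for replicate 1 peaks, and with an overlap of 50% of both peaks that of replicate 2 peaks was 36.0%. With peaks of q of 0.001 or less in each list, 21 of 22 replicate 2 peaks and 7.19% of replicate 1 peaks were shared. Across those 21 peaks r was 0.71 (0.403 to 0.874), an interval that overlaps that of the main r.

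Replicated peaks were also set against the 2308 pooled chromosomal peaks that were not in the replicated list. The replicated peaks at Gnas, the imprinted locus of the stimulatory G protein alpha subunit, were 6 in number and covered 2487 bases. Replicated peaks lay in the bodies or promoters of protein-coding genes more often, at 48.5% against 41.7%. They were wider, with a median of 327 against 244 bases, and had a median fold of 2.97 against 2.72. The permutation tests gave adjusted p-values of 1.67e-05 for each of these, which rest on the smallest p the permutations can give. Mean GC content was 46.4% against 45.8% (adjusted permutation p = 0.00109), a difference much smaller than the SD of 6.14% among replicated peaks. The rule behind the replicated list was not given, so whether width or fold were among its criteria is unknown. Of the 2345 other pooled peaks, scaffolds included, 0 overlapped peaks of both replicates, so such overlap was tied to being in the replicated list. The differences in width and fold cannot be separated from that selection. The permutations shuffled single peaks as independent although peaks cluster, so their p-values may be too small.

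The next comparison asked where in genes the mark lay. Exons of protein-coding genes, outside promoters, held 235 of 2210 replicated peaks by midpoint. This was the feature with the highest ratio to rotation, 3.76. Last exons of zinc finger genes held 104 replicated peak midpoints. First exons of the clustered protocadherin subfamilies Pcdhga and Pcdhgb had 27 and 12 replicated peaks. Of these peaks, any with a midpoint in a promoter were not counted as exon. Whether exons exceed rotation without these gene families was not tested. Wide exonic peaks covered the last exon of Dact3, a modulator of Wnt signalling, over 870 bases at fold 5.02, and an exon of Zfhx3, a homeobox and zinc finger transcription factor, over 1714 bases at fold 5.14. The promoter and an exon of Cdkn1c, an imprinted cell cycle inhibitor, lay under a peak of 1141 bases at fold 3.58. The exon share was 10.6% against 2.83% in rotations (adjusted permutation p = 0.0008) and the promoter share was 5.93% against 4.00% (adjusted permutation p = 0.0052). Intergenic sequence, here all sequence outside protein-coding genes and their promoters, held 51.5% against 58.0% (adjusted permutation p = 0.016). Introns held 31.9% against 35.2%, which did not pass (adjusted permutation p = 0.153). In the longer replicate 1 list alone, the exon ratio was 1.51, the promoter excess ended (1.02), the intron deficit passed (0.884, adjusted permutation p = 0.0004) and the intergenic share turned to an excess that passed (1.04, adjusted permutation p = 0.0008); in the replicate 2 list the exon ratio was 6.65. In the whole pooled list, the promoter excess (1.16) and the intergenic deficit (0.948) no longer passed. Replicated peaks held fewer repeat-masked bases than rotations did, 21.7% against 33.8%. The feature ratios were not corrected for this, so they do not separate the place of the mark from where reads could be placed.

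Among 12 gene lists, zinc finger genes and imprinted genes carried replicated peaks more often than rotation gave. Of 428 zinc finger genes, 82 had a peak (19.2%), against a mean of 9.24 in rotations, a ratio of 8.87. Of 59 imprinted genes, which are expressed from the allele of a single parent, 16 had a peak (27.1%) against 2.33, a ratio of 6.87. Both adjusted permutation p-values were 0.0012. The 16 imprinted genes rested on 21 peaks, 5 of them found in both replicates. Peaks were shared by Commd1 and Zrsr1, Kcnq1 and Kcnq1ot1, Airn and Igf2r, and Blcap and Nnat. The Nespas peak lies inside Gnas. The 16 genes are therefore fewer separate places, although rotations count overlapping genes in the same way. In the lists of single replicates, the zinc finger ratio was 2.07 in replicate 1 and 15.7 in replicate 2, and the imprinted ratio was 2.35 and 9.61. Among replicated peaks, no other list passed. None of the 38 stomach epithelium genes, 39 Hox genes or 33 housekeeping genes had a replicated peak, but rotations gave means of only 0.576, 0.181 and 0.350, so no depletion was detectable.

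The zinc finger genes with the highest folds were Zfp606 (4.67), Zfp110 (4.66), Zfp90 (4.66), Zfp992 (4.64), Zfp369 (4.54) and Zfp873 (4.54). Zfp110 on chromosome 7 (12834761 to 12850577) had 11 replicated peaks, and Zfp873 on chromosome 10 (82048123 to 82064745) had 15. Zfp992 lies inside the long non-coding gene Gm26573, so its 5 peaks were shared with that gene. Zinc finger genes within 200 kb of another member had a peak in 58 of 279 cases (20.8%), against a rotation mean of 4.43, a ratio of 13.1. The others had a peak in 24 of 149 (16.1%), against 4.81, a ratio of 4.99. The shares were close, and the gap in ratio lay mainly in the rotation means.

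The imprinted genes with the highest folds were Cdkn1c, Commd1 and Zrsr1, each at 3.58, followed by Gnas, Grb10 and Kcnq1, each at 3.34. The peak of 886 bases on chromosome 11 (22971867 to 22972752) covered the promoter of Zrsr1, which lies inside an intron of Commd1, and was found in both replicates at folds of 3.39 and 3.57. At Grb10, which encodes an adaptor that dampens growth factor signalling, a peak of 516 bases lay at a promoter, and replicate 2 had no peak in the gene. The peak of Kcnq1, a potassium channel gene, spanned 495 bases in an intron, within an exon of the antisense RNA gene Kcnq1ot1, on chromosome 7 (143250812 to 143251306). With peaks of q of 0.05 or less only, the imprinted list no longer passed (ratio 6.12, adjusted permutation p = 0.163).

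The remaining lists had few peaks or a wide spread in rotations. Olfactory receptors, the odorant receptors of the nose, had no replicated peak in 1135 genes against a mean of 5.92 (adjusted permutation p = 0.0544), and passed in the pooled list with 2 genes against 11.98 (adjusted permutation p = 0.0256). In the replicate 1 list, 44 olfactory receptor genes had a peak, a ratio of 0.802 (adjusted permutation p = 0.531). Vomeronasal receptors had 3 of 329 genes against 4.47 (adjusted permutation p = 1), among them Vmn2r105. Clustered protocadherins, neuronal cell adhesion genes in a single locus, had 18 of 57 genes against 3.63, with rotations reaching up to 22 (adjusted permutation p = 0.358), and passed in the replicate 1 list with 43 genes against 20.8 (adjusted permutation p = 0.012). Pcdhga1 to Pcdhga5 and Pcdhga10 lay under the same peak of fold 5.02. Germline genes had 3 of 40 against 0.814 (adjusted permutation p = 0.262): the RNA-binding protein gene Dazl (fold 3.34), Taf7l (3.34) and the piRNA pathway gene Piwil1 (2.73). When only promoters were counted, the protocadherins (adjusted permutation p = 0.0016) and germline genes (adjusted permutation p = 0.0366) passed. The germline call rested on 2 genes against a mean of 0.12. These were Dazl and Taf7l, whose peaks had a −log10 q of 0.698 and no partner in the replicate 2 list. In the list of smooth muscle, enteric neuron and mesenchyme genes, 1 of 34 had a peak, the PDGF receptor gene Pdgfrb (fold 2.72). Of intestine, lung and brain genes, 1 of 34 had a peak, the vesicular glutamate transporter gene Slc17a7 (fold 4.06), and of the 39 liver, pancreas, spleen and blood genes none had 1. Each of these lists had an adjusted permutation p of 1.

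**Figure D1:**
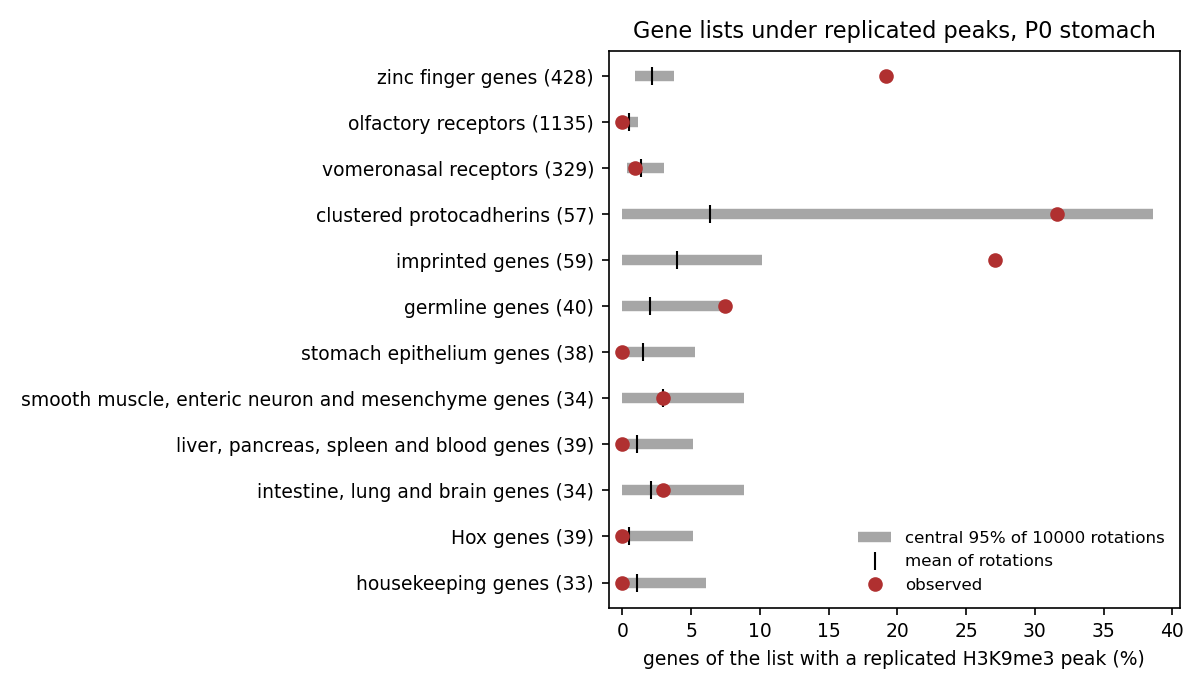
Share of the genes of each list with a replicated H3K9me3 peak (red points, %), with the mean (black mark) and central 95% (grey bar) of 10000 rotations; list sizes are in parentheses. Zinc finger genes lie at 19.2% and imprinted genes at 27.1%, both outside their bars, whereas the protocadherins at 31.6% lie inside a wide bar.

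Within zinc finger genes, the question was whether the peaks lay on the last exon, which usually encodes the zinc finger array. Of 214 replicated peaks in these genes, 104 (48.6%) had their midpoint in a last exon. Zfp606 had 3 of 4 peaks there, Zfp873 had 4 of 15, Zfp110 had 3 of 11 and Zfp90 its single peak of 1643 bases. Zfp992 had none of 5. Last exons took 9.83% of the bases of the gene bodies, and rotations gave 10.6% (two-sided permutation p = 0.015). The share stayed high but did not pass with the shorter lists, at 58.4% for peaks of q of 0.05 or less (permutation p = 0.0983), 61.0% for peaks of both replicates (permutation p = 0.105) and 60.9% in replicate 2 alone (permutation p = 0.0647).

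Of the replicated peaks in genes, the highest fold was 7.30, at AC149090.1 on an unplaced scaffold, followed by Gm21887 on chromosome X (6.97) and Tmem267, a transmembrane protein gene (6.73). The local background there was 3.98, 1.54 and 2.12 times that of the genome, and the Gm21887 peak had another near-identical copy. The highest fold at Gm21887 was 3.40 in the replicate 2 list and 8.36 in the replicate 1 list, and at Tmem267 it was 4.09 and 8.88. Without peaks of high background, the highest fold left at Tmem267 was 4.06. The highest fold of all, 8.50, belonged to a peak on chromosome 17 (13305799 to 13306198) that overlapped no gene and was chosen after its values were seen. Klf14 (5.86) and Mvb12b (5.62), which encodes a subunit of an endosomal sorting complex, had a local background of 1.00 times the genome. The folds were 5.31 at Gm49692, 5.26 at Gm26573, 5.14 at Zfhx3, 5.02 at Gm26672, which lies across the Pcdhg genes, and 5.02 at Dact3. The local background was 3.45 times the genome at the Gm49692 peak and 1.00 times at the others. The Gm26573 peak had no partner in the replicate 2 list, which held 10 peaks elsewhere in that gene. The peak of AW822073 (4.90) had 4 near-identical copies and no replicate 2 peak. The zinc finger genes Zfp606, Zfp110, Zfp90, Zfp992, Zfp873 and Zfp369, the pseudogene Gm13230 (4.59), Plec (4.66) and Def8 (4.54) completed the 20, with 1 gene taken for each peak.

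Peaks were unevenly spread over the chromosomes. Chromosome 17 had 1.65 replicated peaks per Mb (1.39 to 1.93), chromosome 18 had 1.61 and chromosome 7 had 1.27, against 0.835 for the genome. Of the 141 peaks on chromosome 18, 75 lay in a single window of 1 Mb at the clustered protocadherins, so its rate rests largely on that locus. Chromosome X had 0.184 and chromosome Y 0.0454, with 4 peaks. Neither rate was corrected for the copies of X and Y in tissue pooled over both sexes, nor for sequence where reads could not be placed. The low values therefore do not show that the mark was scarce there. No test was made, because peaks cluster and the exact Poisson intervals treat them as independent.

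The densest window, on chromosome 18 from 37000001 to 38000000, held 75 replicated peaks over 41.7 kb at the clustered protocadherins. In the replicated list, the first exons of these genes, which encode the part of each protein outside the cell, differed between subfamilies. All 12 Pcdhga genes and all 6 Pcdhgb genes had a replicated peak on the first exon, and none of the 14 Pcdha, 22 Pcdhb and 3 Pcdhgc genes did. In the replicate 1 list, 2 Pcdha, 10 Pcdhb and 1 Pcdhgc first exons had a peak as well, and in the pooled list 1 Pcdha and 1 Pcdhb. In the replicate 2 list, 6 of the 12 Pcdhga and all 6 Pcdhgb first exons had a peak. Of the 75 replicated peaks, 27 lay on Pcdhga and 12 on Pcdhgb first exons, and the rest lay off the first exons. Of the 75 peaks, 24 were found in both replicates. The gene models Gm37013, Gm37388 and Gm42416 share all 75 peaks, and Pcdhga1 shares 67, so peaks could not be assigned to single genes by gene body. The contrast among subfamilies was noticed in the data and not tested.

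**Figure D2:**
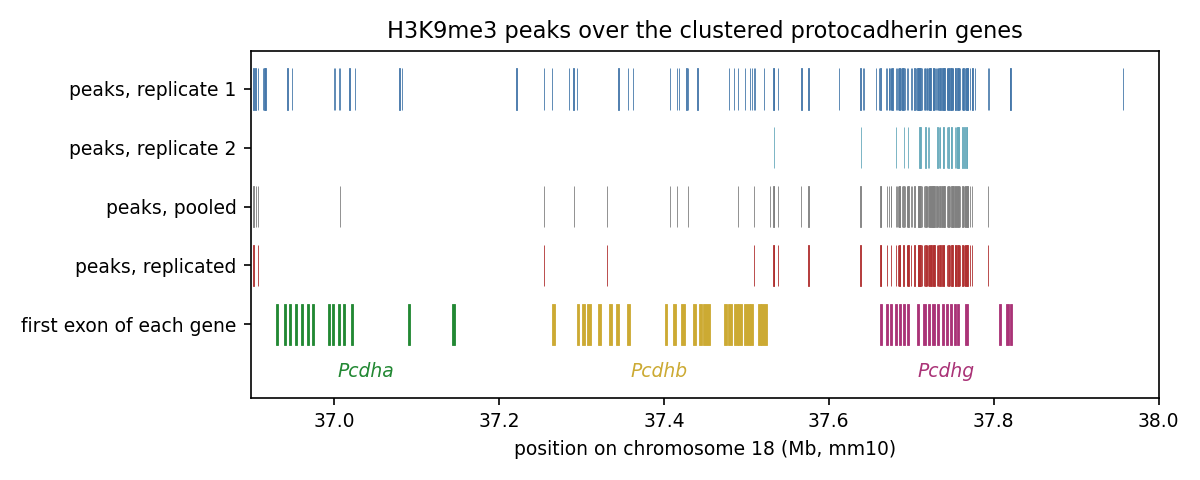
Peaks of each list (bars, to scale) and the first exon of each clustered protocadherin gene along chromosome 18 (Mb, mm10). Replicated peaks fall on the first exons of 12 Pcdhga and 6 Pcdhgb genes, and also between them. They fall on none of the 14 Pcdha and 22 Pcdhb first exons.

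The next window, on chromosome 1 from 88000001 to 89000000, held 50 peaks over 30.7 kb, with 26 at Mroh2a, 11 at the cold-sensing channel gene Trpm8 and 6 shared by Ugt1a10 and Ugt1a2, which encode glucuronidation enzymes from overlapping gene models. Its median local background was 3.98 times that of the genome. The window on chromosome 10 from 81500001 to 82500000 held 44 peaks over 20.3 kb, with 15 at Zfp873, 6 at AU041133, 6 at Gm10778 and 4 at Gm4924, at a median background of 1.00 times. The 10 densest windows together held 313 of 2210 peaks, or 14.2% (12.8 to 15.7, Wilson interval). The interval treats peaks as independent and windows as fixed, although peaks cluster and the windows were chosen from these same peaks.

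**Figure D3:**
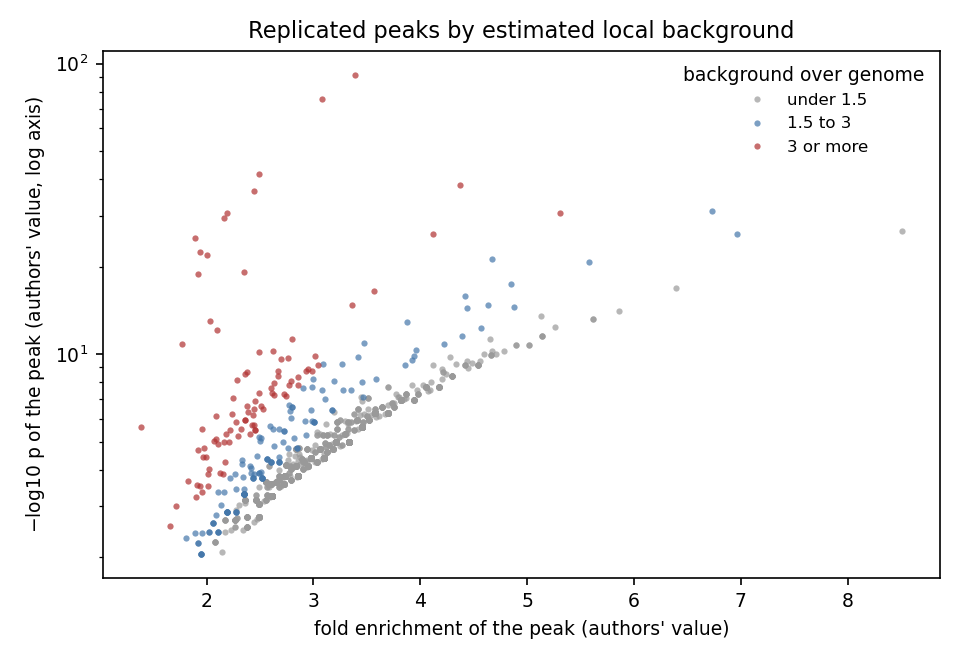
Fold enrichment of each replicated chromosomal peak against its −log10 p (log axis), both as the authors gave them, coloured by the estimated local background relative to the genome. The highest −log10 p, 91.7 on chromosome 17, belongs to a peak of fold 3.39 with a background of 31.1 times the genome.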

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

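The tests on background, read weight, fold steps and 50-base matches, and both tests of the strongest peaks, were chosen only after the results were seen. The tests of weak peaks, of copies at zinc finger genes and of GC content and length were also added once the lists had been viewed, but their bounds were written before their own values were computed. No biological explanation was tested, because the design has a single group. For 3 tests an earlier form was run first and replaced once its value was known; both values are given.

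Signal appeared on sequence outside the chromosomes, which no comparison used. There, 114 replicated peaks lay on 13 scaffolds, 60 of them (52.6%) found in both replicates, against 17.6% of those on chromosomes. This difference was not tested. AC149090.1 had 3 such peaks, with a fold of up to 7.30.

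The lists differed 27.3-fold in length between replicates. Scaling of replicate 2 before calling may account for part of it, since 1 of its reads appeared to weigh 0.491 of a replicate 1 read. Of the weakest 3854 replicate 1 peaks, 20 (0.519%) were found in replicate 2 against 0.0102% in rotations, an excess of 0.509 percentage points, and of the strongest 3854 peaks 6.15% were. Since the short replicate 2 list held only 1.83% of all replicate 1 peaks, this test decided nothing on chance calls, which stay open, as does deeper sequencing of replicate 1. The first depth test, the step between fold values, gave a ratio of 1.53, which went against deeper sequencing by its own bound but mixes depth with read weight, and its replacement, background without scaling, gave 0.737, inside the range that fragment sizes allow.

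Peaks at zinc finger genes, such as Zfp606 and Zfp873, were weighed against shared reads and gene composition. Without peaks that had another near-identical copy, the test run first, the ratio to rotation was 8.92, but this removed no gene from the 82 and so decided nothing. Its replacement, without peaks holding 50 bases found elsewhere, left 80 genes and a ratio of 8.87. Lists matched on GC content and length had a mean of 8.56 genes, which the zinc finger genes exceeded 9.58 times (permutation p = 0.0002, the smallest possible). The matched lists argue against GC content or length of the genes as the whole cause. Of the 214 peaks in zinc finger genes, 11 held 50 bases found elsewhere, which argues against identical runs of that length as the whole cause. Read length and allowed mismatches were not given, so reads shared through shorter or imperfect matches stay open.

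The 30 strongest peaks by p lay at 19 loci, when peaks within 1 Mb were joined, with 8 at the start of chromosome 11 at Drg1 and Sfi1. Of these peaks, 16 had a background of 3 times the genome or more, a bound set after the backgrounds had been viewed, against 3.44% of the other 2180. The choice of peaks by p favours high background by itself: with backgrounds shuffled over the peaks, 25.8 of 30 passed the bound on average (23 to 28), so this test says nothing for or against extra copies beyond the assembly. The first form of the test, the share of peaks with another copy in the assembly, gave a ratio of 2.69 from a single peak in the 30 and decided nothing. Extra copies and misplaced reads both stay open.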

How the results depend on the processing

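Peaks of q of 0.05 or less, peaks of both replicates, peaks without copies or with low background, and zinc finger genes outside clusters were alternatives chosen after seeing the data. Of the values that answer a comparison, 207 kept direction and call, 20 reversed, 9 newly passed, 7 no longer passed and 3 moved; of values for single genes or chromosomes, 374 differed by less than the spread between replicates or the counting interval and 61 by more. The sharing of peaks and the excess of zinc finger genes kept direction and call under every alternative run. Zinc finger ratios ran from 2.07 to 15.7 with a single replicate's list. Values below are ratios to rotation unless named, and the cause was not tested. At q of 0.001 or less, the correlation moved to 0.71 (0.403 to 0.874, from 21 peaks). The spread is wide for some genes that counted as unmoved: the highest fold of Gm21887 ran from 3.40 to 8.36 and that of Tmem267 from 4.09 to 8.88 over single lists. With all pooled peaks, promoters (1.16) and intergenic sequence (0.948) no longer passed, olfactory receptors passed (0.167), vomeronasal receptors (1.02) and liver genes (1.17) turned above 1, and intestine genes turned below (0.713). Leaving out each replicate in turn, ranges were 1.02 to 1.83 for promoters, 1.51 to 6.65 for exons, 0.845 to 0.884 for introns, 0.760 to 1.04 for intergenic sequence, 1.22 to 1.47 for vomeronasal receptors, 2.35 to 9.61 for imprinted genes, 0 to 0.802 for olfactory receptors, 2.07 to 17.0 for protocadherins, which passed in the replicate 1 list, 0 to 1.12 for stomach genes, 0 to 1.07 for liver genes, 0 to 3.91 for Hox genes, which also passed in the replicate 1 list, and 37.4% to 60.9% for last exons. Smooth muscle genes, with 1 gene hit, turned below 1 at 0 with the 1105 peaks of highest fold, 0 at q of 0.05 or less, 0 for peaks of both replicates, 0 for promoters only, 0.699 with independent placement, 0.820 with 5 kb added and 0.987 by Fisher's exact test. Intestine genes turned to 0.931 with independent placement and 0.987 by Fisher's exact test. Germline genes fell to 0 at q of 0.05 or less and 0 for peaks of both replicates, and passed at 16.7 for promoters only. Independent placement let introns (0.908) and olfactory receptors (0) pass. Promoters only let protocadherins pass (84.7). Fisher's exact test, which ignores clusters, let protocadherins (10.9) and olfactory receptors (0) pass. At q of 0.05 or less, imprinted genes (6.12) and last exons (58.4%) no longer passed, nor did last exons for peaks of both replicates (61.0%); these lists held fewer peaks, 468 and 389. The 10 densest windows moved to 16.3% with the peaks of highest fold and 12.7% with windows of 0.5 Mb. Read depth was unknown, so its limit could not be set.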

Other observations

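The tests in this part were chosen after the data had been seen, apart from that of Hox genes in a single replicate, and no explanation is offered.

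In the replicate 1 list alone, 8 of 39 Hox genes, the transcription factor genes that pattern the body axis, had a peak (adjusted permutation p = 0.0132): Hoxa11, Hoxc4, Hoxc5, Hoxc9, Hoxc10, Hoxd1, Hoxd3 and Hoxd4. Their folds ran from 2.08 at Hoxd1 to 3.39 at Hoxd3 and Hoxd4, and the highest −log10 q among them was 0.925. The 8 genes rested on 7 separate peaks, because the peak of Hoxd3 is also that of Hoxd4 and those of Hoxc9 and Hoxc10 lie within Hoxc5. No Hox gene had a peak in the replicate 2, pooled or replicated list.

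Repeat-masked bases made up 21.7% of replicated peaks against 33.8% in rotations (permutation p = 0.0002, the smallest possible). Rotations could place peaks on any base that is not N, whether or not reads could be placed there. The deficit therefore does not tell a lack of the mark in repeats from a lack of placed reads. Within 500 kb of the first base of a chromosome that is not N lay 49 peaks, 2.22% of the total, in 0.397% of the genome. These peaks came from 10 chromosomes, and 20 of them lay on chromosome 4 (3050095 to 3228683). The window of 1 Mb at the start of chromosome 11 held 14 peaks, at a median background of 31.2 times the genome. The excess was therefore concentrated at few chromosome starts. Of 671 gene families scanned by symbol, Zfp alone passed, with 80 of 394 genes (adjusted permutation p = 0.0134), a set that overlaps the zinc finger list. The Ugt family had 9 of 22 genes, all at the Ugt1a locus (adjusted permutation p = 1).

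Background reads without scaling were 2.84 per position in replicate 1, 3.85 in replicate 2 and 6.57 in the pooled list, where the replicates add to 6.69.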
